A study of Mus musculus with 13 samples.

How the data were processed

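RNA was sequenced from fibroblasts of mouse lung. The design of the series calls those of all 4 groups Col1a1-GFP fibroblasts, that is, cells of mice in which a collagen promoter drives a green fluorescent protein. Per the labels of the single libraries the input was 200 ng of total RNA and TruSeq v2 kits were used. For the 10 sham and bleomycin libraries they add Col1a1-GFP mice of 8 weeks, an RNA quality number of at least 6, poly(A) selection and 12 PCR cycles, which they do not state for the 3 pneumonectomy libraries. These are called primary sorted fibroblasts, and any difference in preparation that goes with this cannot be separated from pneumonectomy. The labels state neither a sorting gate nor the sex of the mice. The 13 libraries formed 4 groups: sham (n = 2), day 14 after bleomycin (n = 3), day 30 after bleomycin (n = 5) and day 14 after pneumonectomy (n = 3). The numbers in the labels link each sham and bleomycin library to its column, whereas the 3 pneumonectomy columns carry no replicate number and are called A, B and C here.

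The deposited values are RPKM, read counts divided by gene length and library depth, computed by the authors for 43346 genes on the mouse mm10 assembly. The aligner, the read counter and the annotation were not given in the sources used here. Read counts were not used here, and all 13 columns of values were used. Entries whose symbol occurred more than once (131) were kept as separate entries, had no gene length assigned and were passed over when genes were named. All 37 mitochondrial genes were listed at 0 in all libraries. A single gene, Gm23935, named after its values were seen, took 4.57% to 13.6% of a library's summed RPKM.

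Depth was read from the values themselves. Ratios between libraries of values under 0.03 RPKM gave the relative depth, and gene lengths from GENCODE mouse release M21 set its absolute level. The number of reads behind the library-depth term was 67.5 M to 200.1 M per library, of which 32.4 M to 96.2 M lay on genes with a length. As a check, 38512 values of genes with few estimated reads were divided by the gene's smallest value, corrected for depth. With that smallest value taken as 1 or 2 reads, 99.9% were whole reads within 0.01. The smallest values themselves pass this check by construction. 1 read in a 2-kilobase gene was worth 0.00740 RPKM in the shallowest library and 0.00250 RPKM in the deepest. Such limits cover counting error alone, since PCR reads without molecular identifiers are not independent molecules.

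Genes with at least 1 RPKM in at least 2 libraries were kept (12938 genes, 11230 of them protein-coding). RPKM values were scaled between libraries with factors of the trimmed-mean-of-M-values type (trimming 30% of ratios and 5% of levels), and 0.1 was added before taking log2. All 13 libraries entered 1 linear model with a mean per group, fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with an intensity trend, robust), and 5 contrasts were drawn from it. Adjusted p values are Benjamini-Hochberg values over all genes tested, called at 0.05, and two-sided. Log2 changes are given with the standard error of the fit, and levels as the mean of the deposited RPKM with SD. Because the model shares its spread over all groups, a contrast with the 2 sham libraries rests on the assumption that sham varies like the other groups.

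The comparisons, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined, on the assumption of read counts. As only RPKM were at hand, the planned count model was replaced by the limma fit on RPKM. The pseudocount, the filter and the scaling were then chosen before any call was seen. The planned Wald test on counts could not be run.

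The genes named below follow a rule with 4 parts. Part 1 takes up to 6 genes per direction with the largest log2 change among called genes with a mean of at least 5 RPKM in the higher group and no overlap between the groups' libraries, passing over predicted or clone-named genes and segments of immunoglobulin and T-cell receptor genes. Part 2 takes up to 5 called members of each list with the smallest p, part 3 a fixed panel of 11 genes, and part 4 the 3 most abundant members of each other-cell list with a called test. The minimum was planned as 5 CPM and applied as 5 RPKM. Any other gene is said to have been chosen after its values were seen.

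The 28 gene lists comprised pathways and fibroblast states, 9 lists of markers of other cell types and a list of sex-linked genes. Each was tested with camera on the scaled log2 values at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and tested again with the correlation estimated from the data. Counts of members called over all genes are given beside counts adjusted over the list alone. Principal components were computed from the 1000 most variable kept genes. Overlaps between comparisons that share libraries were set against 20 simulated data sets without group differences and, as a check chosen after seeing the data, counted again with the libraries of the shared group divided between the contrasts.

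The fit was tested on simulated data with 200 changed genes. At a log2 change of 1 it recovered 76.1% to 91.0% of them across the 5 comparisons, and at 2 it recovered 90.9% to 100%, with 1.97% to 5.85% of calls false. The bound for recovery at a change of 2 was first set at 95% and was lowered to 85% after recoveries of 90.9% in 2 comparisons with sham missed it. The simulated values were drawn on the scaled log2 scale with normal noise and the same spread in all groups. They therefore test neither the scaling nor the assumption that sham varies like the other groups. Far more genes were called in the real data, so the share of false calls need not carry over.

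Alternatives comprised median-of-ratios and upper-quartile scaling, the RPKM as deposited with a pseudocount of 1 or 0.1, limma-voom on reads estimated from the RPKM, no filter, a filter of 1 CPM of estimated reads in 3 libraries, a fit of the compared groups alone, the replicate number as a block, a test against a fold change of 1.5, removal of a trend with gene length, and leaving out each library in turn. A pseudocount of 1 on the scaled values and a fit without the genes that follow endothelial markers were added after seeing the data. Figures and simple summaries were made with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9, and tables were handled with version 1.17.8 of data.table.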

Results

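Gene expression was measured by RNA sequencing in fibroblasts, described for the series as Col1a1-GFP, from the lungs of mice after sham treatment (n = 2), 14 days (n = 3) and 30 days (n = 5) after bleomycin, a drug that injures the lung and leads to scarring, and 14 days after pneumonectomy (n = 3), the removal of a lung, after which the remaining lung grows. Depth, as the reads behind the deposited RPKM, was 67.5 M and 71.9 M in the sham libraries, 79.8 M to 99.8 M at day 14 after bleomycin, 132 M to 200.1 M at day 30 and 68.9 M to 75.4 M after pneumonectomy. On the mm10 assembly Col1a1 lies on chromosome 11 from 94936224 to 94953042, Cthrc1 on chromosome 15 from 39076932 to 39087121, Acta2 on chromosome 19 from 34241090 to 34255590 and Tcf21 on chromosome 10 from 22817281 to 22820174. On the first principal component, which held 57.8% of the variance, the day 14 bleomycin libraries lay at 59.8 to 65.0 and all other libraries at -36.3 to -8.56. The second component (22.8%) separated the pneumonectomy libraries at 29.5 to 34.8 from the day 30 bleomycin libraries at -28.1 to -18.6. Spearman correlations across genes were 0.964 to 0.991 between libraries of a group.

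**Figure D1:**
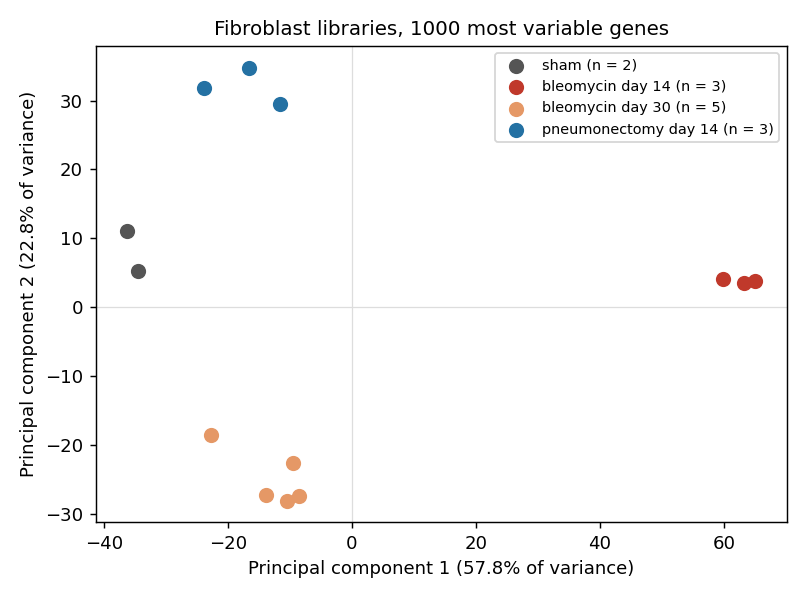
Position of each of the 13 libraries on the first and second principal components (log2 of scaled RPKM, 1000 most variable genes, points colored by group). The 3 day 14 bleomycin libraries sit at 59.8 to 65.0 on the first component, apart from the other 10 libraries.

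The sex of the mice differed between groups. Xist, the RNA of the inactive X chromosome, was at 19.9 to 29.2 RPKM in all 5 day 30 libraries, and the Y-linked Ddx3y, Kdm5d, Eif2s3y and Uty were listed at 0 there. In the day 14 bleomycin and pneumonectomy libraries Xist was at 0.00448 to 0.0222 RPKM and Ddx3y at 9.91 to 23.8. Sham replicate 1 held both, with Xist at 15.9 and Ddx3y at 2.14 RPKM, whereas sham replicate 2 had Xist at 0.0147 and Ddx3y at 11.4. By these genes, the comparison of day 30 with day 14 was also one of female with male mice, that of day 30 with sham set female mice against 1 male and 1 mixed library, and the return toward sham carries the same difference. Of 5 sex-linked genes tested between day 30 and day 14, 2 were higher and 3 lower.

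The first comparison asked how fibroblasts changed 14 days after bleomycin. Spp1, which encodes osteopontin, was at 1118 ± 349 RPKM against 2.61 ± 0.418 in sham, a log2 change of 8.39 ± 0.38 (SE; n = 3 and 2). Grem1, an antagonist of BMP signaling, changed by 7.14 ± 0.41 (4.42 with a pseudocount of 1), Tnc (tenascin C) by 6.10 ± 0.41 and Cthrc1 by 3.30 ± 0.41, the last at 40.2 ± 6.84 RPKM against 3.48 ± 1.52. The proliferation gene Mki67 was at 5.45 ± 0.656 RPKM against 0.125 ± 0.0397. Gsn, the actin-severing protein gelsolin, was at 282 ± 69.8 RPKM against 5889 ± 424.

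In the fibrotic fibroblast list, 16 of 22 members were higher, 4 lower and 2 not called (17 and 4 adjusted over the list alone). The list's median log2 change was 2.95 (camera adjusted p = 0.0014, and adjusted p = 0.702 with an estimated correlation). Its members Runx1, a transcription factor, and Postn (periostin) changed by 3.66 ± 0.26 and 1.22 ± 0.24. In the fibrillar matrix list, 19 of 40 members were higher, 9 lower and 12 not called (19 and 9 adjusted over the list alone), and the list was not called (adjusted p = 0.535). Col1a1 was at 1373 ± 230.1 RPKM against 554 ± 165 (log2 change 1.08 ± 0.31, adjusted p = 0.00947), a call that was lost without sham replicate 1 (0.77, adjusted p = 0.104). Col1a2 and Col3a1 differed by 0.29 ± 0.26 and -0.02 ± 0.25 and were not called. Within the same list P4ha3, a subunit of the collagen prolyl hydroxylase, rose by 4.72 ± 0.40, whereas the proteoglycans Dcn (decorin) and Lum (lumican) and the collagen Col14a1 changed by -3.79 ± 0.25, -2.25 ± 0.16 and -3.97 ± 0.30.

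In the cell cycle list, 36 of 37 members were higher, 0 lower and 1 not called (36 and 0 adjusted over the list alone), with a median of 3.07 (adjusted p = 3.75e-16, and adjusted p = 0.557 with an estimated correlation). Plk1, a mitotic kinase, changed by 3.95 ± 0.19 and Ccna2, cyclin A2, by 3.51 ± 0.18. Their sham levels were 0.148 and 0.487 RPKM, and 1 of the 37 members was above 5 RPKM in both sham libraries. The size of the changes in this list therefore depends on the pseudocount of 0.1. In the adventitial fibroblast list, 0 of 24 members were higher, 21 lower and 3 not called (0 and 21 adjusted over the list alone), with a median of -2.96 (adjusted p = 1.46e-08, and adjusted p = 0.557 with an estimated correlation). Its members Pi16, Scara5 and Ebf2 changed by -4.07 ± 0.27, -4.90 ± 0.31 and -4.74 ± 0.31. Vit, an extracellular matrix gene outside that list, changed by -5.18 ± 0.46.

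In the alveolar fibroblast list, 9 of 28 members were higher, 10 lower and 9 not called (10 and 10 adjusted over the list alone), and the list was not called (adjusted p = 0.71). Tcf21, a transcription factor of lung lipofibroblasts, was at 10.5 ± 2.40 RPKM against 36.5 ± 0.937, and Inmt changed by -3.97 ± 0.24. The median of this list was -0.21 and turned to 0.04 on the scale as deposited. Pdgfra, a growth factor receptor, changed by -1.06 ± 0.15. In the contractile list, 8 of 25 members were higher, 10 lower and 7 not called (8 and 10 adjusted over the list alone), with a median of -0.33 (adjusted p = 0.538). Acta2, smooth muscle actin, was at 258 ± 22.4 RPKM against 417 ± 197. Its log2 change of -0.86 ± 0.28 (adjusted p = 0.0194) was no longer called on the scale as deposited (-0.61), with the compared groups alone (adjusted p = 0.0607), with the replicate block (-0.77) or without sham replicate 1 (-0.36). Myh11 and Lmod1, which are genes of smooth muscle, changed by -2.23 ± 0.35 and -2.14 ± 0.32, and the tropomyosin Tpm4 by 1.20 ± 0.11.

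Interferon-stimulated genes gave 13 higher and 3 lower of 23, 13 and 3 adjusted over the list alone (median 0.92, adjusted p = 0.0129, and adjusted p = 0.702 with an estimated correlation). Isg15 changed by 2.10 ± 0.29 and Oas1a by 3.25 ± 0.32. The interferon score, in log2 relative to sham, was 1.35 in bleomycin day 14 replicate 2 and 0.64 and 0.67 in replicates 1 and 3, and the macrophage score was 2.88 in replicate 2 and 1.25 and 2.30 in the others. Glycolytic genes gave 14 higher and 3 lower of 20, 14 and 3 adjusted over the list alone (adjusted p = 0.00568, and adjusted p = 0.557 with an estimated correlation), with Ldha at 1.53 ± 0.13 and Pkm at 1.34 ± 0.11. Cholesterol synthesis genes gave 12 higher and 2 lower of 21, 12 and 2 adjusted over the list alone (adjusted p = 0.0308, and adjusted p = 0.702 with an estimated correlation). The cholesterol call was lost without sham replicate 2 (adjusted p = 0.149) or bleomycin day 14 replicate 1 (0.0671). Immediate-early genes gave 1 higher and 19 lower of 24, 1 and 19 adjusted over the list alone (adjusted p = 0.00296, and adjusted p = 0.702 with an estimated correlation), with Egr1 at -2.21 ± 0.24 and Nr4a1 at -1.62 ± 0.35. That call was lost without sham replicate 1 (adjusted p = 0.0558).

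Several lists held members that moved apart and were not called. Of the p53 target list, 10 of 22 members were higher, 3 lower and 9 not called (10 and 3 adjusted over the list alone), at adjusted p = 0.0933, and the cell cycle inhibitor Cdkn1a was at 46.4 ± 6.89 RPKM against 12.8 ± 1.73, with Phlda3 at a change of 1.29 ± 0.09. In the list of TGF-beta targets, 9 of 25 members were higher, 13 lower and 3 not called (9 and 13 adjusted over the list alone), at adjusted p = 0.346. Tgfb1, the ligand itself, changed by 2.24 ± 0.15 and Tgfbi by -2.95 ± 0.26. In the inflammatory list, 9 of 25 members were higher, 10 lower and 6 not called (9 and 10 adjusted over the list alone). Its median was -0.22 and its mean 0.20, the camera direction was down (adjusted p = 0.932), and the median turned to 0.03 on the scale as deposited. Saa3, an acute-phase gene, rose by 5.61 ± 0.33, while complement C3 and the chemokine Ccl11 changed by -3.66 ± 0.23 and -3.70 ± 0.38. In the lists of matrix degradation and of prostaglandin and cyclic nucleotide genes, the median (-0.19 and -0.14) and the camera direction were down and the mean (0.43 and 0.05) was above 0, and both medians turned on the scale as deposited. In the lymphocyte, airway epithelial and sex-linked lists the test also differed in sign from the median or the mean. Of growth factors that act on lung epithelium, Hgf rose by 1.18 ± 0.23 and Wnt2b changed by -4.79 ± 0.32.

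Markers of other cells changed too. Of the endothelial list, 19 of 20 members were higher, 0 lower and 1 not called (19 and 0 adjusted over the list alone), with a median of 5.00 (adjusted p = 4.71e-09, and adjusted p = 0.557 with an estimated correlation). Cdh5 (VE-cadherin) was at 100.3 ± 31.1 RPKM against 0.998 ± 0.553, and Cldn5 and Plvap changed by 6.56 ± 0.41 and 4.32 ± 0.39. Of the macrophage list, 17 of 21 members were higher, 0 lower and 4 not called (17 and 0 adjusted over the list alone), with a median of 2.38 (adjusted p = 4.71e-04, and adjusted p = 0.702 with an estimated correlation). Lyz2 was at 210.1 ± 108 RPKM against 15.8 ± 4.58, Ctss changed by 3.77 ± 0.51 and Chil3 by 2.68 ± 0.73. Of the granulocyte markers, 6 higher and 0 lower of 9, 6 and 0 adjusted over the list alone, and of the erythroid markers, 3 higher and 0 lower of 4, 3 and 0 adjusted over the list alone, and neither list was called (adjusted p = 0.187 and 0.258).

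In all, 8177 of 12938 genes differed between day 14 after bleomycin and sham, 4257 higher and 3920 lower, of which 1533 and 1320 changed over 2-fold. Without the 561 higher genes that were as low in bleomycin replicate 1 relative to replicates 2 and 3 as the endothelial markers were, an alternative chosen after seeing the data, 7610 genes differed. As the 561 were called genes, their removal lowers the count by itself and does not show how far endothelial RNA shapes the calls. The scale as deposited moved the median gene to 0.26 and gave 6193 higher and 2451 lower genes. The calls rest on 2 sham libraries, and 2767 genes passed a test against a 1.5-fold change.

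**Figure D2:**
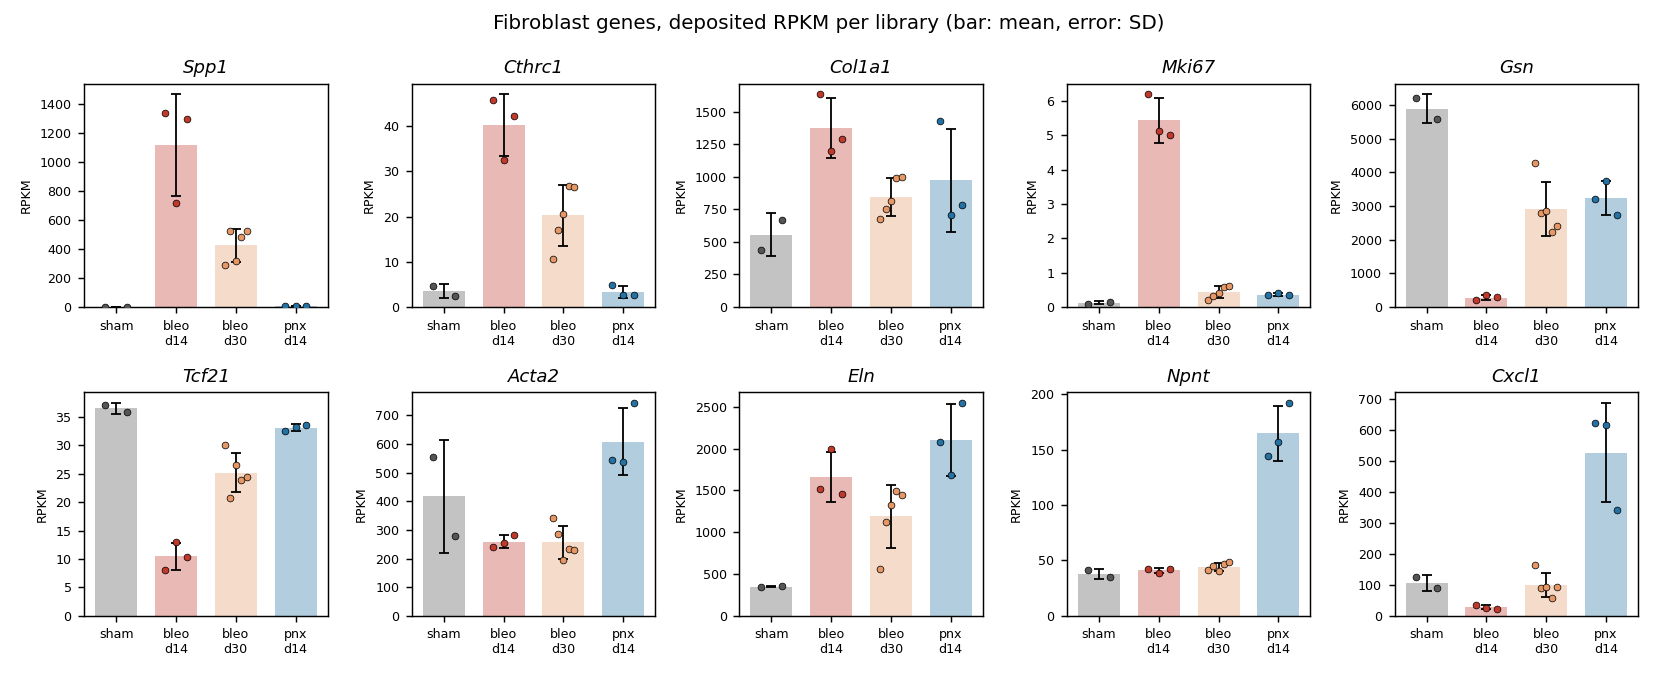
Deposited RPKM of 10 fibroblast genes in each library (points), with group means (bars) and SD (error lines), for sham (n = 2), bleomycin day 14 (n = 3), bleomycin day 30 (n = 5) and pneumonectomy day 14 (n = 3). Cthrc1 had a mean of 40.2 RPKM at day 14 after bleomycin and 3.37 after pneumonectomy, and Npnt a mean of 165 RPKM after pneumonectomy.

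The next comparison asked how fibroblasts changed 14 days after pneumonectomy. Of the inflammatory, alveolar fibroblast and fibrillar matrix lists, 17 of 25, 18 of 28 and 25 of 40 members were higher, and the calls of these lists were lost with an estimated correlation. The chemokine Ccl2 was at 108 ± 22.4 RPKM against 8.03 ± 0.642, a log2 change of 3.92 ± 0.27 (SE; n = 3 and 2), and Cxcl2 changed by 4.62 ± 0.37. Eln (elastin) was at 2101 ± 432 RPKM against 349.9 ± 9.93, and Npnt (nephronectin), a basement membrane ligand of integrin alpha 8, at 165 ± 24.6 RPKM against 37.9 ± 4.56. Thbs1, which encodes a thrombospondin, changed by 4.14 ± 0.35 and Hk2, a hexokinase, by 4.55 ± 0.37. Without sham replicate 1 the changes of Cxcl2, Thbs1 and Hk2 were 5.30, 4.83 and 5.15, and without sham replicate 2 they were 3.94, 3.45 and 3.95. Cthrc1, at 3.37 ± 1.33 RPKM against 3.48 ± 1.52, was not called (0.16 ± 0.41, adjusted p = 0.775).

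In the inflammatory list, 17 of 25 members were higher, 3 lower and 5 not called (17 and 3 adjusted over the list alone), with a median of 2.36 (adjusted p = 9.16e-06, and adjusted p = 0.275 with an estimated correlation). The adhesion molecule Vcam1 and the chemokine Cxcl5 changed by 2.59 ± 0.19 and 3.37 ± 0.27. In the alveolar fibroblast list, 18 of 28 members were higher, 0 lower and 10 not called (19 and 1 adjusted over the list alone), with a median of 1.14 (adjusted p = 2.65e-07, and adjusted p = 0.0695 with an estimated correlation). Col13a1, Fgfr4, Limch1 and Ces1d changed by 2.58 ± 0.09, 2.50 ± 0.13, 1.83 ± 0.13 and 1.67 ± 0.11. Tcf21 was not called (0.07 ± 0.17), and its sign turned under upper-quartile scaling, on the scale as deposited and with the length trend removed. In the adventitial fibroblast list, 1 of 24 members was higher, 16 lower and 7 not called (1 and 18 adjusted over the list alone), with a median of -1.14 (adjusted p = 9.16e-06, and adjusted p = 0.444 with an estimated correlation). Pi16, Cd248 and Ly6c1 changed by -1.85 ± 0.27, -1.85 ± 0.19 and -1.98 ± 0.29.

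In the fibrillar matrix list, 25 of 40 members were higher, 3 lower and 12 not called (25 and 4 adjusted over the list alone), with a median of 0.64 (adjusted p = 2.68e-04, and adjusted p = 0.503 with an estimated correlation). Lox, which crosslinks collagen and elastin, rose by 2.09 ± 0.27, Col6a1 by 1.04 ± 0.15 and Bgn (biglycan) by 0.88 ± 0.13. Col1a1 and Col3a1 changed by 0.98 ± 0.31 and 0.80 ± 0.25 (adjusted p = 0.0248 and 0.0229). Both calls were lost without sham replicate 1 (0.67 and 0.48), without pneumonectomy library A (0.66 and 0.57), with the compared groups alone and on the scale as deposited with a pseudocount of 1, and that of Col3a1 also with a pseudocount of 0.1 (0.59) and with the length trend removed (0.64). Col1a2, at 0.60 ± 0.26, was not called but was called without sham replicate 2 (0.90). In the contractile list, 19 of 25 members were higher, 1 lower and 5 not called (22 and 1 adjusted over the list alone), with a median of 0.75 (adjusted p = 9.16e-06, and adjusted p = 0.431 with an estimated correlation). Cdh11, Mylk, Vcl (vinculin) and Tpm1 changed by 1.69 ± 0.23, 1.25 ± 0.18, 1.06 ± 0.14 and 0.98 ± 0.17. Acta2 changed by 0.82 ± 0.28 (adjusted p = 0.0359), and its call was lost without sham replicate 2 (0.32), without any of the 3 pneumonectomy libraries (0.69 to 0.89), with the compared groups alone, without a filter (0.82), with upper-quartile scaling (0.71) and on the scale as deposited (0.61).

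In the list of TGF-beta targets, 14 of 25 members were higher, 1 lower and 10 not called (14 and 2 adjusted over the list alone), with a median of 0.55 (adjusted p = 4.01e-04, and adjusted p = 0.0722 with an estimated correlation). Its members with the smallest p included repressors of the pathway. Tgif1 changed by 2.31 ± 0.14, Smad7 by 2.09 ± 0.15 and Skil by 1.62 ± 0.16. In the fibrotic fibroblast list, 12 of 22 members were higher, 1 lower and 9 not called (13 and 1 adjusted over the list alone), with a median of 1.05 (adjusted p = 8.69e-04, and adjusted p = 0.464 with an estimated correlation). Tnc changed by 4.30 ± 0.41, Runx1 by 3.22 ± 0.26, Ltbp2 by 2.76 ± 0.36 and Postn by 1.31 ± 0.24. YAP/TAZ targets gave 10 higher and 3 lower of 23, 11 and 3 adjusted over the list alone (adjusted p = 0.0237, and adjusted p = 0.232 with an estimated correlation), a call lost without sham replicate 2 (adjusted p = 0.0631) or library C (0.0514).

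Growth factors that act on lung epithelium gave 11 higher and 3 lower of 24, 11 and 5 adjusted over the list alone (adjusted p = 0.0592). Hgf was at 9.98 ± 2.26 RPKM against 2.90 ± 0.0365, Ereg (epiregulin) changed by 3.81 ± 0.34, Bmp5 by 1.59 ± 0.15 and Wnt5a by -1.35 ± 0.12. Among the largest falls were the WNT ligands Wnt2b and Wnt10b, at -2.58 ± 0.32 and -2.48 ± 0.21, and the WNT antagonist Sfrp4, at -2.36 ± 0.32. Of the matrix degradation list, 16 of 28 members were higher, 5 lower and 7 not called (17 and 5 adjusted over the list alone), at adjusted p = 0.00472, and adjusted p = 0.287 with an estimated correlation, with the proteases Adamts4 and Adamts1 at 4.22 ± 0.36 and 1.38 ± 0.21. Glycolytic genes gave 11 higher and 0 lower of 20, 11 and 0 adjusted over the list alone (adjusted p = 4.01e-04, and adjusted p = 0.232 with an estimated correlation), with the glucose transporter Slc2a1 at 2.59 ± 0.22. Prostaglandin and cyclic nucleotide genes gave 11 higher and 3 lower of 22, 12 and 3 adjusted over the list alone (adjusted p = 0.0131, and adjusted p = 0.141 with an estimated correlation).

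Immediate-early genes gave 11 higher and 0 lower of 24, 11 and 0 adjusted over the list alone (adjusted p = 0.00263, and adjusted p = 0.571 with an estimated correlation), with Nr4a2 at 2.91 ± 0.41 and Ier5 at 1.96 ± 0.17. Cholesterol synthesis genes gave 12 higher and 1 lower of 21, 12 and 1 adjusted over the list alone (adjusted p = 0.00444, and adjusted p = 0.517 with an estimated correlation). Both calls were lost without sham replicate 2 (adjusted p = 0.332 and 0.211). Cell cycle genes gave 9 higher and 2 lower of 37, 8 and 1 adjusted over the list alone (median 0.32, adjusted p = 0.0315, and adjusted p = 0.686 with an estimated correlation), a call lost without sham replicate 1 (adjusted p = 0.102). Mki67 stood at 0.365 ± 0.0355 RPKM against 0.125 ± 0.0397. Its change of 1.23 ± 0.30 was not called without sham replicate 1 (1.05), with voom (1.77) or on the scale as deposited with a pseudocount of 1 (0.28). Of the p53 targets, 10 higher and 5 lower of 22, 10 and 5 adjusted over the list alone (adjusted p = 0.0592), with Cdkn1a at 1.46 ± 0.13 and Gdf15 at 1.89 ± 0.20. Pdgfra was not called (0.25 ± 0.15). Interferon genes gave 2 higher and 1 lower of 23, 1 and 1 adjusted over the list alone, and genes of secretion and the unfolded-protein response 2 higher and 1 lower of 25, 2 and 0 adjusted over the list alone. The sign of both medians (0.15 and 0.07) turned on the scale as deposited (-0.05 and -0.14), and neither list was called (adjusted p = 0.833 and adjusted p = 0.535).

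Markers of other cells changed here as well. Of the endothelial list, 15 of 20 members were higher, 1 lower and 4 not called (17 and 1 adjusted over the list alone), with a median of 1.47 at adjusted p = 2.31e-04, and adjusted p = 0.504 with an estimated correlation, and Cdh5, at 4.81 ± 2.39 RPKM against 0.998 ± 0.553, lay far under its level at day 14 after bleomycin. Cldn5 and Plvap changed by 2.04 ± 0.41 and 1.66 ± 0.39. The calls of Cdh5 and Plvap were lost without sham replicate 2 (1.77 and 1.31), and that of Plvap also with the compared groups alone (adjusted p = 0.0574). Of the pericyte list, 8 of 17 members were higher, 1 lower and 8 not called (8 and 1 adjusted over the list alone), at adjusted p = 0.00891, and adjusted p = 0.517 with an estimated correlation, a call lost without sham replicate 2. Of these 17 members, 4 are also in other lists, among them Postn and Mylk, which are counted above as well. In both sham libraries 8 of the 17 were above 5 RPKM, so a change of this list need not come from other cells. Of the mesothelial list, 8 of 12 members were higher, 2 lower and 2 not called (8 and 3 adjusted over the list alone), at adjusted p = 0.0891, with Upk3b at 3.20 ± 0.59 and Msln at 3.77 ± 0.67, the latter 4.46 without sham replicate 1 and 3.08 without sham replicate 2. Of the macrophage list, 0 of 21 members were higher, 4 lower and 17 not called (0 and 4 adjusted over the list alone). Its median was 0.30 and its mean 0.08, while the camera direction was down (adjusted p = 0.94), and C1qa changed by -2.15 ± 0.41, which was not called with voom (-2.43). Of 15 alveolar epithelial markers 2 were higher and 0 lower (median 2.56, adjusted p = 0.0592), of 6 airway epithelial markers 0 and 0 (median 2.11, adjusted p = 0.259), and of 4 lymphocyte markers 1 and 0 (median 0.48, adjusted p = 0.282), and none of these lists was called. Scgb1a1 of the airway and Sftpc of the alveolar epithelial list, both named after their values were seen, were not called (4.44 and 2.84) but were without day 30 replicate 3 (adjusted p = 0.0243 and 0.0256), the latter also with the compared groups alone (0.0373), so whether both are called depends on that library of another group. The airway epithelial score, in log2 relative to sham, was 4.10, 1.77 and 0.74 in libraries A, B and C. In the sex-linked list the median and the mean also differed in sign.

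In all, 5476 genes differed between pneumonectomy and sham, 2794 higher and 2682 lower, of which 961 and 290 changed over 2-fold. The scale as deposited moved the median gene to -0.21 and gave 1762 higher and 5185 lower genes, upper-quartile scaling moved it to -0.12 and gave 2177 and 3994, and removal of the length trend gave 2169 and 3689. With the compared groups alone 3537 genes differed, without sham replicate 2 it was 3403, and 719 passed the test against a 1.5-fold change.

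**Figure D3:**
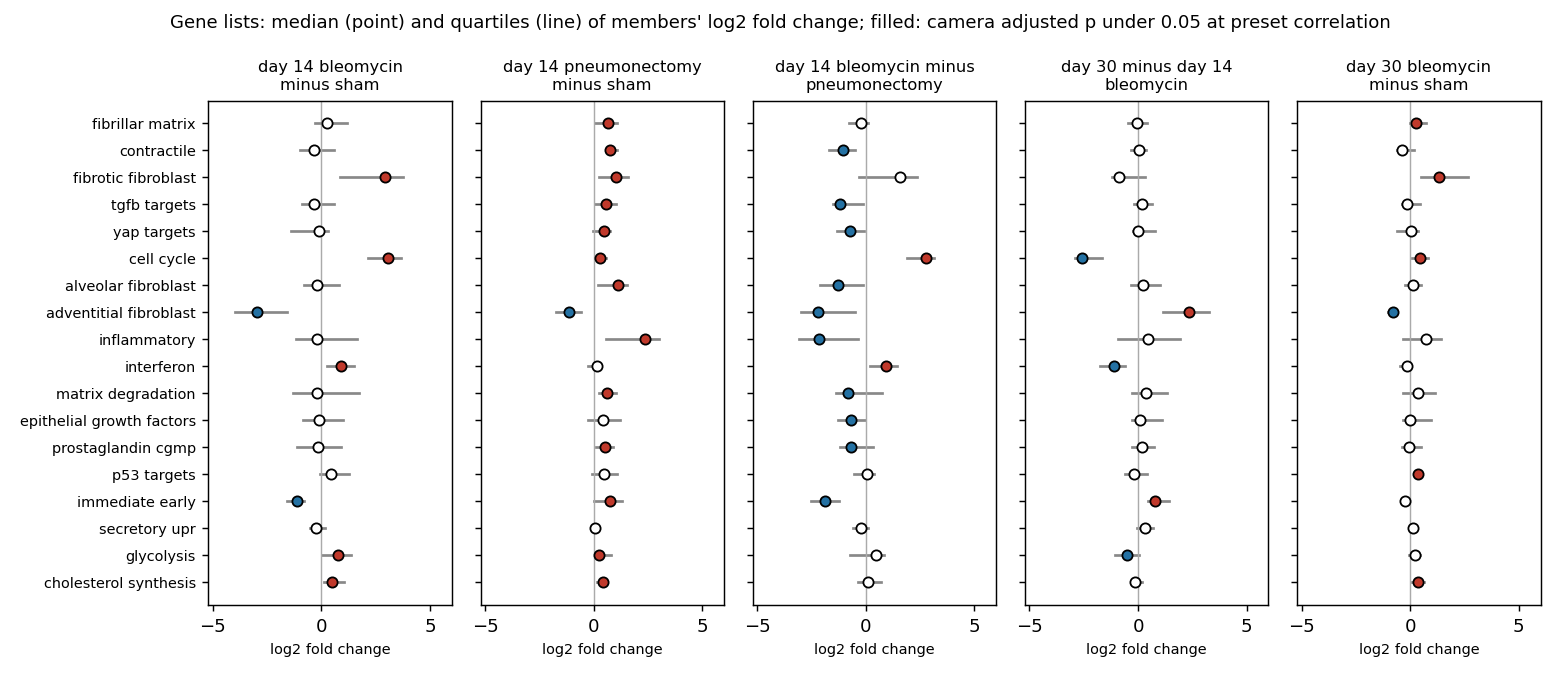
Median (points) and quartiles (lines) of the log2 changes of the members of 18 gene lists in each of the 5 comparisons. Filled points mark lists called by camera at the preset correlation, and none was called with an estimated correlation. The cell cycle list had a median of 3.07 at day 14 after bleomycin and 0.32 after pneumonectomy.

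Both injuries were also compared with sham as overlaps. At day 14, 1324 genes were higher and 1234 lower than sham after both bleomycin and pneumonectomy (2558 in total), against 919 and 813 for independent draws of the same sizes. Another 1076 genes were called in opposite directions. The log2 changes had a covariance of 0.34 against 0.03 in simulated data with the same shared sham libraries and no group differences. In such data 0 genes overlapped after adjustment, an outcome fixed in advance, and a mean of 185 at an unadjusted p of 0.05 (limma). The 0 is therefore no measure of the overlap to be expected when many genes change. The share of genes with the same sign (58.4%) and the correlation (0.42) lay under the simulated values of 70.2% and 0.60. With a different sham library in each contrast, 1748 or 1500 genes were called in the same direction against 1227 or 943 for independent draws, 946 or 559 were called in opposite directions, 55.9% or 56.9% of genes had the same sign, and the correlation was 0.32 or 0.36. Without sham replicate 2 the overlap was 1507 genes.

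The direct comparison of the injuries at day 14 asked what sets fibroblasts of the scarring lung apart from those of the regrowing lung. Spp1 was at 1118 ± 349 RPKM against 6.87 ± 2.83 after pneumonectomy, a log2 difference of 6.90 ± 0.34 (SE; n = 3 and 3), and Cthrc1 and Grem1 differed by 3.14 ± 0.37 and 4.85 ± 0.37. Most members of the inflammatory and alveolar fibroblast lists were lower after bleomycin. Cxcl1 was at 27.8 ± 7.13 RPKM against 527 ± 161, and Has1 (hyaluronan synthase 1) and Tnfaip6, a hyaluronan-binding protein, differed by -5.17 ± 0.51 and -5.15 ± 0.48. Acta2 was at 258 ± 22.4 RPKM against 609 ± 117. Col1a1 and Col1a2 differed by 0.10 ± 0.28 and -0.31 ± 0.23 and were not called.

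In the cell cycle list, 36 of 37 members were higher, 0 lower and 1 not called (36 and 0 adjusted over the list alone), with a median of 2.79 (adjusted p = 9.34e-14, and adjusted p = 0.295 with an estimated correlation). Mki67, Plk1 and Ccna2 differed by 3.17 ± 0.27, 3.70 ± 0.17 and 3.12 ± 0.16. In the contractile list, 1 of 25 members was higher, 20 lower and 4 not called (1 and 20 adjusted over the list alone), with a median of -1.05 (adjusted p = 2.48e-04, and adjusted p = 0.483 with an estimated correlation). Myh11, Myl9 and Flna (filamin A) differed by -3.04 ± 0.31, -1.99 ± 0.22 and -1.52 ± 0.16. In the fibrillar matrix list, 5 of 40 members were higher, 18 lower and 17 not called (5 and 17 adjusted over the list alone), at adjusted p = 0.0564. Its median of -0.24 turned to 0.21 on the scale as deposited. Lum and Loxl1 differed by -1.85 ± 0.14 and -1.20 ± 0.09, and Col3a1 by -0.81 ± 0.22, which was not called on the scale as deposited (-0.36). In the fibrotic fibroblast list, 14 of 22 members were higher, 5 lower and 3 not called (14 and 5 adjusted over the list alone), with a median of 1.58 at adjusted p = 0.070.

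In the alveolar fibroblast list, 3 of 28 members were higher, 17 lower and 8 not called (3 and 17 adjusted over the list alone), with a median of -1.28 (adjusted p = 1.60e-04, and adjusted p = 0.143 with an estimated correlation). Npnt, Fgfr4, Ces1d and Col13a1 differed by -2.44 ± 0.11, -2.46 ± 0.12, -2.08 ± 0.10 and -2.05 ± 0.08, Tcf21 by -2.13 ± 0.15 and Pdgfra by -1.31 ± 0.13. In the adventitial fibroblast list, 3 of 24 members were higher, 18 lower and 3 not called (3 and 18 adjusted over the list alone), at adjusted p = 2.48e-04, and adjusted p = 0.501 with an estimated correlation. Gsn, Scara5 and Serpinf1, an inhibitor of angiogenesis, differed by -3.99 ± 0.26, -3.13 ± 0.28 and -2.90 ± 0.23. Growth factors gave 3 higher and 12 lower of 24, 3 and 12 adjusted over the list alone (adjusted p = 0.0227, and adjusted p = 0.143 with an estimated correlation), with Angpt1 (angiopoietin 1) at -1.84 ± 0.12 and Bmp4 at -1.15 ± 0.12. Hgf differed by -0.75 ± 0.21, which was not called on the scale as deposited (-0.30).

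In the inflammatory list, 5 of 25 members were higher, 17 lower and 3 not called (5 and 17 adjusted over the list alone), with a median of -2.15 (adjusted p = 0.0012, and adjusted p = 0.483 with an estimated correlation). Ptx3 (pentraxin 3), Ccl2, Icam1 and Vcam1 differed by -5.46 ± 0.51, -3.45 ± 0.25, -3.09 ± 0.16 and -2.93 ± 0.17. Sost, a WNT antagonist, differed by -5.25 ± 0.37. Targets of TGF-beta gave 4 higher and 18 lower of 25, 4 and 18 adjusted over the list alone (adjusted p = 0.00113, and adjusted p = 0.143 with an estimated correlation), with Skil at -2.08 ± 0.14, Tgif1 at -1.70 ± 0.13 and the oxidase Nox4 at -1.52 ± 0.09. YAP/TAZ targets gave 4 higher and 16 lower of 23, 4 and 16 adjusted over the list alone (adjusted p = 0.00533, and adjusted p = 0.143 with an estimated correlation), with Gadd45b at -3.35 ± 0.18. Immediate-early genes gave 0 higher and 22 lower of 24, 0 and 22 adjusted over the list alone (adjusted p = 8.99e-06, and adjusted p = 0.483 with an estimated correlation), with Nr4a2, Egr1 and Klf6 at -3.80 ± 0.37, -2.09 ± 0.21 and -1.93 ± 0.16. Interferon genes gave 16 higher and 3 lower of 23, 16 and 3 adjusted over the list alone (adjusted p = 0.0157, and adjusted p = 0.657 with an estimated correlation), with Oas1a at 2.64 ± 0.28 and Irf1 at -2.54 ± 0.32.

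Matrix degradation genes gave 9 higher and 18 lower of 28, 9 and 18 adjusted over the list alone (adjusted p = 0.0497, and adjusted p = 0.483 with an estimated correlation), with Mmp2 at -2.35 ± 0.10 and Timp2 at -1.49 ± 0.12. This call, near the threshold, was lost without sham replicate 1 or 2, bleomycin day 14 replicate 2 or 3, day 30 replicate 2, 3 or 5, or pneumonectomy library A (adjusted p = 0.0501 to 0.0830). Prostaglandin and cyclic nucleotide genes gave 6 higher and 14 lower of 22, 6 and 14 adjusted over the list alone (adjusted p = 0.0393, and adjusted p = 0.178 with an estimated correlation), with prostacyclin synthase Ptgis at -1.74 ± 0.12 and the natriuretic peptide receptor Npr2 at -1.32 ± 0.06. The last call was lost without pneumonectomy library C (adjusted p = 0.0511). Of glycolytic genes 13 higher and 6 lower of 20, 13 and 6 adjusted over the list alone (adjusted p = 0.233), and the list's median of 0.45 and mean of -0.04 differed in sign. Its member Hk2 differed by -4.78 ± 0.33. Of p53 targets 8 higher and 8 lower of 22, 8 and 8 adjusted over the list alone (adjusted p = 0.801). Phlda3 and Bax were higher after bleomycin (1.87 ± 0.08 and 1.27 ± 0.10), Gdf15 was lower (-2.06 ± 0.18) and Cdkn1a was not called (0.14 ± 0.12), though it was on the scale as deposited (0.59).

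The same contrast held the markers of other cells. Of the endothelial list, 19 of 20 members were higher, 0 lower and 1 not called (19 and 0 adjusted over the list alone), with a median of 3.09 at adjusted p = 7.64e-07, and adjusted p = 0.483 with an estimated correlation, with Egfl7, Cldn5 and Cdh5 at 4.88 ± 0.34, 4.53 ± 0.37 and 4.00 ± 0.45. Of the macrophage list, 16 of 21 members were higher, 0 lower and 5 not called (16 and 0 adjusted over the list alone), at adjusted p = 5.78e-04, and adjusted p = 0.508 with an estimated correlation, with C1qa at 4.65 ± 0.37 and Lyz2 at 2.78 ± 0.50. Of the mesothelial list, 0 of 12 members were higher, 12 lower and 0 not called (0 and 12 adjusted over the list alone), at adjusted p = 5.58e-04, and adjusted p = 0.434 with an estimated correlation, with Upk3b at -3.59 ± 0.53. Pericyte markers gave 0 higher and 11 lower of 17, 0 and 11 adjusted over the list alone (adjusted p = 0.0155, and adjusted p = 0.508 with an estimated correlation), and erythroid markers 4 higher and 0 lower of 4, 4 and 0 adjusted over the list alone (adjusted p = 0.0495, and adjusted p = 0.483 with an estimated correlation). The pericyte list shares 4 of its 17 members, among them Myh11, with other lists. Of granulocyte markers, 6 higher and 1 lower of 9 (adjusted p = 0.102), of alveolar epithelial markers 2 higher and 0 lower of 15 (median -1.52, adjusted p = 0.575), of airway epithelial markers 0 higher and 3 lower of 6 (median -3.06, adjusted p = 0.480), and of lymphocyte markers 1 higher and 2 lower of 4 (median -1.71, adjusted p = 0.638), and none of these lists was called. The erythroid call was lost without bleomycin day 14 replicate 2 (adjusted p = 0.0562), pneumonectomy library C (0.0587), or day 30 replicate 3 or 5 (0.0503 and 0.0501).

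In all, 9161 genes differed between the injuries, 4758 higher and 4403 lower after bleomycin, of which 1270 and 1738 differed over 2-fold. The scale as deposited moved the median gene to 0.47 and gave 7918 higher and 2307 lower genes, and upper-quartile scaling moved it to 0.13. Without the genes that followed the endothelial markers, a removal that by itself lowers the count, 8679 genes differed, and 3269 passed the test against a 1.5-fold change.

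**Figure D4:**
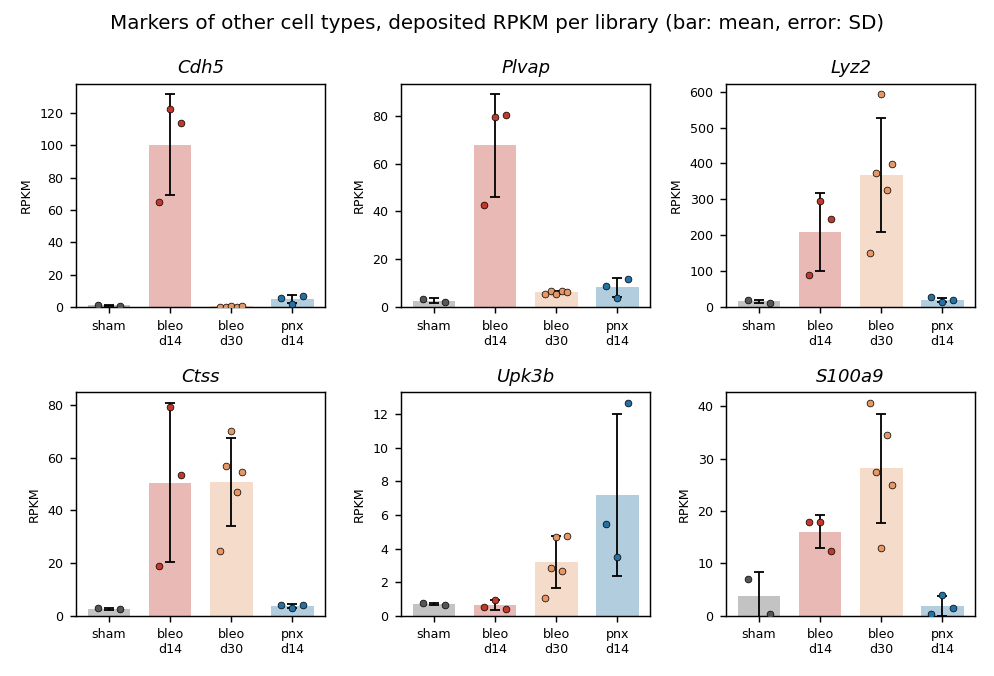
Deposited RPKM of markers of endothelium (Cdh5, Plvap), macrophages (Lyz2, Ctss), mesothelium (Upk3b) and neutrophils (S100a9) in each library (points), with group means (bars) and SD (error lines, which stop at 0). Cdh5 had a mean of 100.3 RPKM at day 14 after bleomycin and 0.365 at day 30, while Lyz2 had means of 210.1 and 368.

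The comparison of day 30 with day 14 after bleomycin asked what changed as time passed after the injury. Gsn was at 2911 ± 811 RPKM against 282 ± 69.8 at day 14, a log2 change of 3.50 ± 0.23 (SE; n = 5 and 3), and Scara5 changed by 3.89 ± 0.25. Mki67 was at 0.429 ± 0.172 RPKM against 5.45 ± 0.656. Col1a1, Col1a2 and Col3a1 were not called (-0.56 ± 0.25, -0.06 ± 0.21 and 0.49 ± 0.20), although Col1a1 was with the compared groups alone (adjusted p = 0.0204) and on the scale as deposited (-0.71), and Col3a1 with upper-quartile scaling (0.50) and the compared groups alone (adjusted p = 0.0123). Leaving out pneumonectomy library A also made both calls (adjusted p = 0.0247 and 0.0246), and leaving out sham replicate 1 or 2 or bleomycin day 14 replicate 1 made that of Col3a1 (0.0364, 0.0362 and 0.0472).

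In the adventitial fibroblast list, 20 of 24 members were higher, 3 lower and 1 not called (20 and 3 adjusted over the list alone), with a median of 2.36 (adjusted p = 1.21e-06, and adjusted p = 0.659 with an estimated correlation). Ebf2, Pi16 and Dcn changed by 3.69 ± 0.25, 3.26 ± 0.22 and 2.93 ± 0.20. In the cell cycle list, 0 of 37 members were higher, 37 lower and 0 not called (0 and 37 adjusted over the list alone), with a median of -2.56 (adjusted p = 9.97e-20, and adjusted p = 0.659 with an estimated correlation). Plk1 and Cdc20 changed by -3.15 ± 0.15 and -3.21 ± 0.17. Interferon genes gave 2 higher and 20 lower of 23, 2 and 20 adjusted over the list alone (adjusted p = 2.84e-05, and adjusted p = 0.659 with an estimated correlation), with Isg15, Irf7 and Oasl2 at -1.95 ± 0.23, -1.95 ± 0.19 and -1.37 ± 0.16. Glycolytic genes gave 3 higher and 12 lower of 20, 3 and 12 adjusted over the list alone (adjusted p = 0.00882, and adjusted p = 0.659 with an estimated correlation), with Pkm at -1.09 ± 0.09. Immediate-early genes gave 15 higher and 2 lower of 24, 15 and 2 adjusted over the list alone (adjusted p = 0.0133, and adjusted p = 0.689 with an estimated correlation), with Egr1 at 1.45 ± 0.19.

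In the fibrotic fibroblast list, 4 of 22 members were higher, 12 lower and 6 not called (4 and 12 adjusted over the list alone), with a median of -0.88 at adjusted p = 0.30. Cthrc1 was at 20.3 ± 6.78 RPKM against 40.2 ± 6.84. Its change of -0.90 ± 0.33 (adjusted p = 0.0333) was not called without bleomycin day 14 replicate 1 (-0.78) or 3 (-0.88), without day 30 replicate 1 (-0.69) or 2 (-0.86), or with no filter (adjusted p = 0.0645). In the fibrillar matrix list, 11 of 40 members were higher, 11 lower and 18 not called (11 and 10 adjusted over the list alone), with a median of -0.03, a mean of 0.12 and a camera direction of up (adjusted p = 0.732). Lum and Col14a1 were among those that rose (2.48 ± 0.13 and 3.29 ± 0.24). In the contractile list, 5 of 25 members were higher, 7 lower and 13 not called (5 and 5 adjusted over the list alone), with a median of 0.02 that turned to -0.12 on the scale as deposited and a camera direction of down (adjusted p = 0.959). Acta2 was not called (0.11 ± 0.23), and its sign turned on the scale as deposited (-0.03).

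Tcf21, Inmt and Pdgfra rose by 1.41 ± 0.13, 2.83 ± 0.19 and 0.68 ± 0.12, though the alveolar fibroblast list, with 14 higher and 6 lower of 28, 14 and 6 adjusted over the list alone, was not called (adjusted p = 0.241). The WNT antagonist Sfrp4 rose by 4.13 ± 0.26, C3 by 3.15 ± 0.18, Ccl11 by 2.68 ± 0.30 and Mmp2 by 1.77 ± 0.09. Cdkn1a and Phlda3 changed by -1.03 ± 0.10 and -0.83 ± 0.07, and Hgf was not called (-0.24 ± 0.19). Of genes of secretion and the unfolded-protein response, 16 higher and 5 lower of 25, 16 and 5 adjusted over the list alone (adjusted p = 0.066).

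Markers of other cells shifted over the same interval. Of the endothelial list, 0 of 20 members were higher, 20 lower and 0 not called (0 and 20 adjusted over the list alone), with a median of -5.34 at adjusted p = 2.31e-13, and adjusted p = 0.659 with an estimated correlation. Cdh5 was at 0.365 ± 0.186 RPKM against 100.3 ± 31.1, Cldn5 changed by -7.11 ± 0.33 and Plvap by -3.25 ± 0.31. Of the mesothelial list, 10 of 12 members were higher, 0 lower and 2 not called (11 and 0 adjusted over the list alone), at adjusted p = 0.00202, and adjusted p = 0.659 with an estimated correlation. Of the macrophage list, 3 of 21 members were higher, 2 lower and 16 not called (0 and 0 adjusted over the list alone), at adjusted p = 0.959, with a median of 0.09 that turned to -0.05 on the scale as deposited. Xist was at 24.6 ± 3.26 RPKM against 0.0111 ± 0.00127. In the lymphocyte and airway epithelial lists the test, the median or the mean differed in sign.

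In all, 7693 genes differed between day 30 and day 14, 3939 higher and 3754 lower at day 30, of which 1010 and 890 changed over 2-fold. The scale as deposited moved the median gene to -0.13 and gave 2785 higher and 5213 lower genes. The test against a 1.5-fold change was passed by 1828 genes. Of the 4257 genes higher and 3920 lower at day 14 than in sham, 3113 (73.1%) fell and 3121 (79.6%) rose again by day 30, 6234 in total, against 1235 and 1193 for independent draws. Another 69 moved further from sham. Endothelial markers, higher at day 14 and lower again at day 30, are among the genes that returned. Simulated data with the same shared libraries and no group differences gave 0, an outcome fixed in advance, and a mean of 148 at an unadjusted p of 0.05 with limma. Among the 2853 genes that changed over 2-fold at day 14, a median of 30.1% of the change remained at day 30. With the 3 day 14 libraries divided between both contrasts in each of 6 ways, 4160 to 4887 genes returned, against 1422 to 1721 for independent draws, 12 to 82 moved further, and 79.9% to 84.2% of all genes had opposite signs in the contrasts.

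Day 30 and pneumonectomy were also set side by side against day 14 after bleomycin. In both, 2840 genes were higher and 2821 lower than at day 14 after bleomycin, against 1341 and 1381 for independent draws, and 408 were called in opposite directions. The changes had a covariance of 0.75 against 0.02 in simulated data, a correlation of 0.75 against 0.56, and the same sign in 77.0% of genes against 68.9%. With the day 14 libraries divided between both contrasts, 3773 to 4554 genes were called in the same direction, against 1609 to 1996 for independent draws, and 134 to 285 in opposite directions, with a correlation of 0.69 to 0.73. On the scale as deposited the genes lower in both numbered 4711.

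The last comparison asked what remained changed 30 days after bleomycin. Spp1 was still at 427 ± 114 RPKM against 2.61 ± 0.418 in sham, a log2 change of 7.16 ± 0.35 (SE; n = 5 and 2). Grem1, at 20.4 ± 7.71 RPKM against 0.0544 ± 0.0342, changed by 6.91 ± 0.38, which was 4.20 with a pseudocount of 1, Tnc by 4.66 ± 0.38, the latent TGF-beta binding protein Ltbp2 by 4.71 ± 0.33 and Cthrc1, at 20.3 ± 6.78 RPKM against 3.48 ± 1.52, by 2.40 ± 0.38. The genes with the largest log2 changes also held Ibsp, a bone matrix sialoprotein, at 7.03 ± 3.13 RPKM against 0.00716 ± 0.0101 (listed at 0 in sham replicate 2), the elastase Mmp12, at 5.28 ± 1.71 RPKM against 0.0127 ± 0.00925, and Igfbp2 (4.71 ± 0.46). For Ibsp and Mmp12, whose sham values were near 1 read, the size of the log2 change is set by the pseudocount and is not given. Macrophage markers were also higher at day 30 than in sham. Whether macrophages gave part of the RNA of Spp1 or Mmp12 at day 30 was not tested. Gsn remained lower than in sham, at 2911 ± 811 RPKM against 5889 ± 424 (-1.16 ± 0.26). Col1a1, Col1a2, Col3a1 and Acta2 were not called (0.52 ± 0.28, 0.23 ± 0.24, 0.47 ± 0.23 and -0.75 ± 0.26), although Acta2 was without sham replicate 2 (-1.25) or day 30 replicate 1 (-0.86), with the length trend removed (-0.91) and under other alternatives near the threshold.

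In the fibrotic fibroblast list, 13 of 22 members were higher, 0 lower and 9 not called (16 and 0 adjusted over the list alone), with a median of 1.33 (adjusted p = 4.45e-08, and adjusted p = 0.443 with an estimated correlation). Postn changed by 1.39 ± 0.22. In the fibrillar matrix list, 12 of 40 members were higher, 3 lower and 25 not called (13 and 3 adjusted over the list alone), at adjusted p = 0.0143, and adjusted p = 0.744 with an estimated correlation, a call lost without sham replicate 1 (adjusted p = 0.0987) and with the replicate block (0.0574). P4ha3, Col7a1 and Col16a1 changed by 3.61 ± 0.37, 3.42 ± 0.48 and 0.87 ± 0.13. In the adventitial fibroblast list, 0 of 24 members were higher, 15 lower and 9 not called (0 and 19 adjusted over the list alone), with a median of -0.81 (adjusted p = 2.80e-06, and adjusted p = 0.706 with an estimated correlation). Cd248 changed by -0.80 ± 0.17. In the contractile list, 1 of 25 members was higher, 6 lower and 18 not called (1 and 7 adjusted over the list alone), at adjusted p = 0.0756.

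In the p53 target list, 10 of 22 members were higher, 1 lower and 11 not called (14 and 2 adjusted over the list alone), with a median of 0.35 (adjusted p = 0.00224, and adjusted p = 0.255 with an estimated correlation). Cdkn2a, a cell cycle inhibitor of senescent cells, was at 1.98 ± 0.798 RPKM against 0.0482 ± 0.0324, and Cdkn1a and Bax changed by 0.57 ± 0.12 and 0.62 ± 0.10. Cell cycle genes gave 15 higher and 0 lower of 37, 17 and 1 adjusted over the list alone (median 0.43, adjusted p = 5.14e-04, and adjusted p = 0.744 with an estimated correlation). Cholesterol synthesis genes gave 11 higher and 0 lower of 21, 12 and 0 adjusted over the list alone (adjusted p = 0.00103, and adjusted p = 0.744 with an estimated correlation), with Cyp51 at 1.30 ± 0.23 and Mvd at 1.06 ± 0.12. This list call was lost without sham replicate 2 (adjusted p = 0.129), without which Cyp51 stood at 0.70, and at 1.90 without sham replicate 1. Tgfb1 rose by 1.51 ± 0.14, and of the alveolar fibroblast list Plin2 and Tbx4 rose by 1.07 ± 0.17 and 1.22 ± 0.20, while Tcf21 changed by -0.65 ± 0.15. The collagenase Mmp13 was at 1.73 ± 0.536 RPKM against 0.0426 ± 0.0133. The median, the mean and the camera direction differed in sign in the lists of TGF-beta targets (median -0.17, mean 0.06, down), YAP/TAZ targets (0.04, -0.02, down), growth factors (-0.01, 0.32, up) and prostaglandin genes (-0.05, 0.10, down), none of them called, and in the airway epithelial and erythroid lists.

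Of macrophage markers, 18 higher and 0 lower of 21, 19 and 0 adjusted over the list alone (median 2.39, adjusted p = 1.99e-09, and adjusted p = 0.443 with an estimated correlation), with Lyz2 at 368 ± 159 RPKM against 15.8 ± 4.58, Ctss at a change of 4.06 ± 0.47 and Chil3 at 3.01 ± 0.67. Replicate 1 of day 30 had the lowest fibrotic fibroblast score (1.48, others 1.98 to 2.37) and the lowest macrophage score (1.75, others 2.14 to 2.88). Beyond it the order differed, with the macrophage score highest in replicate 3 and the fibrotic fibroblast score highest in replicate 4. Of granulocyte markers, 7 higher and 0 lower of 9, 7 and 0 adjusted over the list alone (adjusted p = 0.00246, and adjusted p = 0.443 with an estimated correlation), with S100a9 at 3.79 ± 1.00 (5.79 without sham replicate 1 and 1.79 without sham replicate 2). Of endothelial markers, 2 higher and 1 lower of 20, 0 and 1 adjusted over the list alone (adjusted p = 0.0692).

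In all, 3670 genes differed between day 30 and sham, 2015 higher and 1655 lower, of which 616 and 186 changed over 2-fold. Of the genes called at day 14, 2955 were called in the same direction at day 30, against 663 and 501 for independent draws, and 109 in the opposite direction. Both contrasts share the sham libraries, and the correlation of 0.62 and the share of 74.3% of genes with the same sign were near the simulated values of 0.66 and 72.6%. The covariance of the log2 changes was 0.44 against 0.03 in the simulated data. With a different sham library in each contrast 1662 or 1353 genes were called in the same direction, against 640.4 or 498 for independent draws, and 126 or 75 in the opposite direction, with a correlation of 0.49 or 0.55. The scale as deposited moved the median gene to 0.11 and gave 3105 higher and 957 lower genes, and removal of the length trend gave 1346 and 2052. Without sham replicate 1 or 2 the count was 2347 or 1792, and with the replicate number as a block, in a fit without the pneumonectomy libraries, it was 372 (the cause was not tested). Without a sham library the calls were lost of Gsn (replicate 1, -1.09), Tcf21 (replicate 1, -0.63, and replicate 2, -0.68), and, without replicate 2, Cd248 (-0.79), Cdkn1a (0.43), Chil3 (2.85) and S100a9. With the block the calls of these genes were lost as well as those of Cthrc1 (1.99), Postn (1.13), Col16a1 (0.73), Cyp51 (1.28), Mvd (1.02), Plin2 (0.96) and Tbx4 (1.03).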

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

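All tests weighed here were chosen after the results were seen, except the test for mesothelial cells and both counts of other splits. Of 92 items examined over the 5 day 30 libraries, 10 held a library far from the other 4, by a gap above 0.71 of the range. Chance alone gives about 1 in 20.

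Replicate 3 of day 30 had an alveolar epithelial score of 4.64 (log2 relative to sham, others -0.13 to 0.66), an airway epithelial score of 3.45 (others -0.78 to -0.35), a granulocyte score of 1.28 (others 2.18 to 2.34) and Cdh5 at 0.691 RPKM (others 0.25 to 0.344). Replicate 1 of day 30 had an interferon score of 0.036 (others -0.26 to -0.20), a pericyte score of 0.093 (others 0.67 to 0.81), Ccl11 at 90.1 RPKM (others 35.6 to 49.1) and Egr1 at 356 RPKM (others 198 to 239). Replicate 4 had C3 at 559 RPKM (others 757 to 820.2), and replicate 5 a scaling factor of 0.091 on the log2 scale (others 0.039 to 0.054). The cause of these was not tested.

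By the direct test, 7693 genes differed between day 30 (female by the sex-linked genes) and day 14 (male) after bleomycin. This was a difference of time and sex together. Of the 56 splits of these 8 libraries, 1, the real one, gave as many genes, and the highest other split gave 8. A share of 1 in 56 is under 0.05, which argues against chance as the source of this count but does not exclude it. Splits that mix the groups take the group difference into their spread, so low counts there were to be expected. The splits cannot tell time from sex or depth, which divide these libraries in the same way. Against sham, 1076 genes were called in opposite directions after both injuries and differed between them directly, fewer than the 2558 called in the same direction. With both sham libraries in each contrast, the number expected for independent draws was not computed for this count. With a different sham library in each contrast, fewer genes were called in opposite directions than independent draws would give. No excess of opposite calls can therefore be read from these data. For the 9161 genes that differed between the injuries, the 10 splits of the 6 libraries, of which 1 gave as many and the highest other gave 0, are too few for a share under 0.05.

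Endothelial and macrophage markers were high at day 14 after bleomycin, with Cdh5 at 100.3 RPKM and Lyz2 at 210.1. The 19 endothelial markers that rose were lower in replicate 1 than in replicates 2 and 3 by a median log2 ratio of -0.85 (quartiles -0.98 and -0.71), as endothelial cells in unequal shares would give, and 2 of the list's 20 members were above 5 RPKM in both sham libraries. Fibrotic fibroblast members that rose had a ratio of 0.35 (quartiles 0.16 and 0.47), against -0.85 for endothelial and -1.55 for macrophage markers, and cell cycle members 0.29, which argues against RNA of either source for the first list and of endothelium for the second. The median log2 change of Col1a1, Col1a2, Col3a1 and Pdgfrb was above that of the adventitial list by 3.10. This argues against dilution of fibroblast RNA as the whole cause only as far as these genes did not themselves rise, and Col1a1 was called higher. A part played by dilution stays open. A gate against endothelial and immune surface markers, which the labels do not state, would remove endothelial cells and macrophages.

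The libraries of day 30 and day 14 after bleomycin also differed in sex and depth. With different day 14 libraries behind the 2 shifts, the shift from day 14 to the male pneumonectomy libraries was, over the called autosomal genes, a median of 0.87 times that to day 30 in the lowest of 6 divisions (4949 genes, quartiles 0.41 and 1.31), which argues against sex as the whole cause. Over called genes with at least 5 RPKM the lowest median was 0.89 (2598 genes, quartiles 0.46 and 1.33), with pneumonectomy at lower depth than day 14, which argues against depth as the whole cause. For 1624 genes called between the time points and not between pneumonectomy and day 14, sex and time cannot be told apart, because each group is of 1 sex. Endothelial markers were lower at day 30 than at day 14, with a median log2 change of -5.34. They were higher at day 14 than after pneumonectomy, with a median of 3.09. Dividing the day 14 libraries leaves this RNA in both shifts, so these ratios cannot weigh it. Time after injury stays open as the biological difference, and so do parts played by sex and by endothelial RNA.

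Inflammatory genes were higher after pneumonectomy than in sham, and their 17 risen members were lower in library C than in A and B, at a ratio of -0.54 (quartiles -0.92 and -0.42), whereas mesothelial markers were higher there, at 1.38, which argues against mesothelial cells, of whose 12 markers 3 were above 5 RPKM in both sham libraries. Of 21 macrophage markers 0 were higher than in sham by limma, which argues against macrophages. Scgb1a1, at 418, 61.9 and 9.04 RPKM in A, B and C, Sftpc, at 65.1, 28.6 and 25.1, and Igkc, at 29.3, 20.9 and 14.9, led the airway epithelial, alveolar epithelial and lymphocyte markers, and the median log2 ratio of the excess over sham in A to that in B was 0.10 for inflammatory members (quartiles -0.06 and 0.66), which minus that of the markers gave -2.95, -1.44 and -0.97, and this argues against both epithelia as the whole source and leaves lymphocytes, with 3 markers, open. Handling of the cells before lysis stays open, since Fos, Jun and Egr1 differed by 0.016, 0.011 and -0.12 and Fosb and Junb by 1.46 and 0.62, with a median of 0.016 over 5 genes that went both ways. The value of Fosb rests on 2 sham libraries that lay apart, at 85.6 and 250.8 RPKM. The whole immediate-early list, which holds these 5 genes, was called higher after pneumonectomy, with a median log2 change of 0.77. Handling would give the same direction. The list's call was lost with an estimated correlation and without sham replicate 2. Endothelial markers that rose were higher in library C than in A and B, at 0.70 (quartiles 0.66 and 0.79). Pericyte markers that rose were so too, at 0.38 (quartiles 0.31 and 0.48). With the inflammatory members at -0.54, this argues against either cell type as the whole source. The response to pneumonectomy stays open too, and with these tests handling, lymphocytes and biology cannot be told apart.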

How the results depend on the processing

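The Wald test on counts that had been planned was not run, because read counts were not used, and the replicate block gave no value for the comparisons with pneumonectomy, whose columns carry no numbers. Scaled values with a pseudocount of 1 and the fit without the genes that follow the endothelial markers were chosen after seeing the data. The counts of genes that differed stayed within 1.5 times the values in the report under median-of-ratios and upper-quartile scaling, voom, both other filters, removal of the length trend and both alternatives chosen later. The fit without the genes that follow the endothelial markers takes out called genes by design, so its counts do not test an endothelial source. The genes lower at day 30 and after pneumonectomy than at day 14 after bleomycin numbered 4805 and 4711 on the scale as deposited (pseudocounts 1 and 0.1) against 2821, since that scale raises day 14. With the compared groups alone 3537 genes differed between pneumonectomy and sham, where fewer libraries entered the fit. With the replicate block 372 genes differed between day 30 and sham, in a fit that also left out the pneumonectomy libraries, and the cause was not tested, though the compared groups alone kept 2997 of the calls and the block 364. The block assumes that equal numbers pair libraries, and libraries of the same number correlated at only -0.13 to 0.14 after their group mean was removed. The test against a 1.5-fold change, stricter by construction, left 2767 genes for day 14 against sham, 719 for pneumonectomy against sham, 3269 between the injuries, 1828 for day 30 against day 14 and 326 for day 30 against sham. It left 320 genes shared between the injuries, 668 lower in both at day 30 and after pneumonectomy, and 1583 that returned toward sham. Leaving out each library in turn gave 3403 to 5707 genes for pneumonectomy against sham, the lowest without sham replicate 2, and 1792 to 4050 for day 30 against sham, the lowest without sham replicate 2 and 2347 without sham replicate 1. The overlap of both injuries was 1507 to 2693, the lowest without sham replicate 2. In these fits the lone sham library was assumed to vary like the other groups. The ranges of the other counts were 7025 to 8371 for day 14 against sham, 8511 to 9286 between the injuries, 6585 to 7899 for day 30 against day 14, 2397 to 2881 for the genes lower in both and 5371 to 6414 for the return. Some panel genes that were not called changed sign, and for these the cause was not tested. For day 14 against sham, Col3a1 was 0.23 on the scale as deposited with either pseudocount and 0.069 with the length trend removed, and leaving out a library gave -0.33 to 0.30 for Col3a1 and -0.0061 to 0.59 for Col1a2. For pneumonectomy against sham, Tcf21 was -0.047 with upper-quartile scaling, -0.14 as deposited with either pseudocount and -0.0104 with the length trend removed. Cthrc1 was -0.032 and -0.039 as deposited (pseudocounts 1 and 0.1) and -0.29 to 0.61 when a library was left out. Between the injuries Col1a2 was 0.15 as deposited with either pseudocount and 0.023 with the length trend removed, and Col1a1 was -0.078 to 0.42 when a library was left out. For day 30 against day 14, Acta2 was -0.032 as deposited with either pseudocount, and Col1a2 -0.14 to 0.081 when a library was left out. For day 30 against sham, Col1a2 was -0.069 to 0.53 when a library was left out. Of the list calls, 717 results without a library kept their call and 24 lost it, and with an estimated correlation all 57 calls were lost. Depth limits genes near 1 read, worth 0.0025 to 0.0074 RPKM in a gene of 2 kilobases. The filter asks for 1 RPKM in 2 libraries of any group, so genes near 1 read in sham were kept, and the size of their log2 change is set largely by the pseudocount. It also depends on the pseudocount of 0.1 for genes near that level in sham, such as Plk1, Oas1a, Col7a1 and Igfbp2 (0.148, 0.138, 0.182 and 0.191 RPKM).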

Other observations

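All values given next were chosen after the results were seen, and no explanation of them was tested. Among genes that changed over 2-fold at day 14 after bleomycin, a median of 34.4% of the change remained at day 30 for the 1533 higher genes and 27.9% for the 1320 lower genes, with quartiles of 12.5% and 69.6% and of 17.5% and 40.4%. Gm23935 held 12.1% to 13% of the summed RPKM in the day 14 bleomycin libraries, against 6.02% and 8.47% in sham and 4.57% to 8.84% at day 30, and 13.6% in library C after pneumonectomy against 8.25% and 7.77% in A and B.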
